A study of Mus musculus with 6 samples.

How the data were processed

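RNA-seq was done on 6 libraries of hindlimb satellite cells sorted by flow cytometry, 3 of mice labelled WT and 3 of mice labelled KO for estrogen receptor α in satellite cells, after tamoxifen at 10 mg in total, per the labels. Total RNA was extracted with a Qiagen RNeasy kit and made into Illumina libraries, per the labels' protocols; neither strandedness nor a ribosomal RNA or poly(A) step is given in the sources used here. The submitters' processing notes name CASAVA, Trimmomatic 0.33, FastQC and kallisto, and the builds GRCm38 and mm10, with no role, order or further settings. The annotation behind the quantification is not given in the sources used here. The authors deposited TPM per gene symbol, that is, values scaled for transcript length and for the total of each library; the file does not say how transcripts were summed per gene.

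The table lists 24980 symbols, of which 20506 are above 0 in at least 1 library. The listed TPM add up to between 29.5% and 33.4% of the full TPM scale per library, so the remainder lies in features not used here, and a change in that remainder would move all listed values of a library together. TPM keeps no depth, so no count model was used and the precision of single values is unknown. Small structured RNAs took 39.5% to 45.1% of the listed TPM and the 10 most abundant genes 34.0% to 40.4%. In 26 cases the symbol had been turned into a date; these were kept as listed and none was named. Among genes of mean TPM 1 or more, 17 had values identical to another gene in every library, 15 of them tested, which points to shared reads; near-identical copies such as histone genes are uncertain for the same reason.

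Groups were taken from the labels. The numbers in the sample titles differ between all libraries and pair none of them. Genes with TPM of 1 or more in at least 3 of the 6 libraries were kept, whatever the group, which left 8971, of which 8156 are protein-coding by RefSeq biotype. Values were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. For Esr1 an exact two-sided permutation test was added.

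Gene lists were tested with camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 of 26 lists with at least 3 tested members. The tenocyte, sex-linked and mitochondrially encoded lists had fewer. Beside it, camera with an estimated correlation and fry were run. Of the 7 lists called with the preset correlation, 0 held with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, called 0. Its mixed test, which asks whether they change in either direction, called 3. Members were also counted with adjustment over the list alone. Notch3 is in both the Notch and the pericyte list.

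The groups, the main tests, the lists, the naming rule and the other settings tried were chosen, with the exceptions named below, before the data were examined. The rule named Esr1, then up to 12 genes in each direction past the threshold with groups that did not overlap, or, with fewer than 5 in a direction, the 5 with the smallest p, passing over predicted genes and symbols ending in Rik. It also named up to 4 members of each list with the smallest p. Mki67, Thbs1, Dcn, Acta1, Apba3 and the ribosomal protein-like genes were named after their values were seen. Some genes that the rule names are not reported here.

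Coordinates are those of GENCODE vM21 on GRCm38, matched by symbol, 1-based. The other settings were pseudocounts of 0.1 and 5, other filters (none, a mean TPM of 1, TPM of 5), scaling by the median of ratios, quantile normalization, removal of haemoglobin and ribosomal RNA genes with rescaling, eBayes without a trend or robust, estimated library weights, and leaving out each library in turn. Another, protein-coding genes alone rescaled to a common total, was added after the data were seen. The alternatives that rescale keep the set of genes tested; this was settled after a first run in which the filter was applied after rescaling and other counts were found. That order is given as a further alternative, added after the data were seen, and tests 13538 protein-coding genes or, with haemoglobin and ribosomal RNA genes removed, 13368 genes. Rescaling to a larger total also makes the pseudocount of 1 smaller relative to the values.

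The procedure was tested on simulated data made from the real means and residual spreads, in 5 simulations of KO against WT with between 8975 and 9022 genes tested each. Of 500 genes changed 2-fold 75.2% were called, and of 500 changed 4-fold 95.4%. Among 946 calls 58 were false. Of 25 lists of 25 genes shifted by 0.4 on the log2 scale 25 were called, and of 75 unshifted lists 0. The simulated genes were independent of each other, which real genes are not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.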

Results

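Satellite cells, the muscle stem cells that lie between the fibre and its basement membrane, were isolated by flow cytometry from the hindlimb muscles of adult C57BL6/J mice. The mice had received tamoxifen, 10 mg in total, to induce Cre. RNA-seq was done on 3 libraries labelled WT and 3 labelled KO, in which estrogen receptor α, the product of Esr1, was targeted in satellite cells. The only contrast the design gives is KO against WT, and it asks which transcripts of satellite cells differ when the receptor gene is targeted. The values were TPM, a length-scaled measure of transcript abundance, for 24980 gene symbols. The listed values summed to between 295306 and 334382 TPM per library, and between 39.5% and 45.1% of that sum lay in small structured RNAs such as Rnu6 and Rpph1. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval can be given. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries, which may in part be technical.

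Esr1, the targeted gene on chromosome 10 at 4611593 to 5005614 (GRCm38, plus strand), was lower in every KO library than in any WT library. The WT libraries held 7.53, 6.96 and 6.94 TPM, a mean of 7.14 ± 0.335 (SD, n = 3). The KO libraries held 2.92, 3.69 and 3.87 TPM, a mean of 3.49 ± 0.505 (SD, n = 3), which is 48.9% of the WT mean. The log2 difference was -0.86 (SE 0.13), with an adjusted p of 0.0925 from limma with Benjamini-Hochberg adjustment over all genes tested. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries can give. All 6 libraries therefore had Esr1 on the side their labels name, although the difference did not pass the adjusted threshold. The value is a sum over a gene's transcripts and does not resolve a deleted exon.

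**Figure D1:**
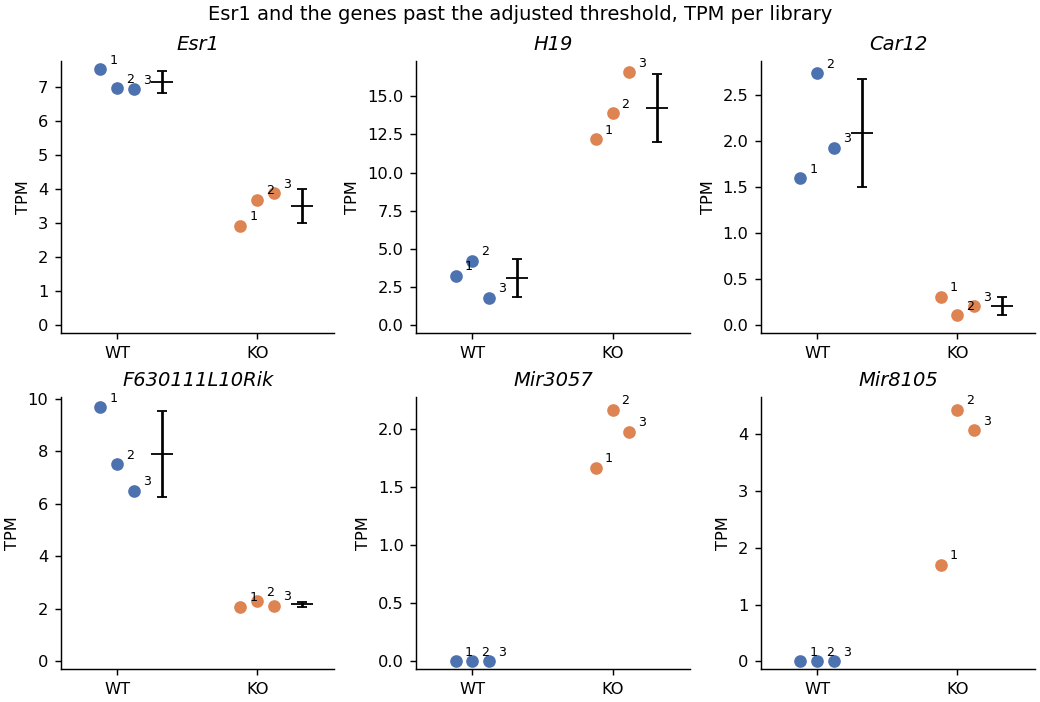
TPM (y axis) in each of the 3 WT and 3 KO libraries (points, numbered by replicate) for Esr1 and the 5 genes past the adjusted threshold; black bars are the group mean ± SD, and none is drawn for the microRNA genes, which are listed at 0 in WT. Esr1 lies between 6.94 and 7.53 TPM in WT and between 2.92 and 3.87 TPM in KO.

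Single genes that passed the adjusted threshold of 0.05 were few: 3 rose and 2 fell in KO among 8971 tested (limma, Benjamini-Hochberg). H19, an imprinted long noncoding RNA expressed from the maternal allele (chromosome 7, 142575529 to 142578143, minus strand), rose from 3.10 ± 1.22 to 14.2 ± 2.21 TPM (SD, n = 3 each; limma adjusted p = 0.0491), a ratio of means of 4.59. Car12, a membrane-bound carbonic anhydrase (chromosome 9, 66713686 to 66766845, plus strand), fell from 2.09 ± 0.587 to 0.21 ± 0.10 TPM (SD, n = 3 each; limma adjusted p = 0.0491), or 10.0% of the WT mean. F630111L10Rik fell from 7.88 ± 1.63 to 2.16 ± 0.112 TPM (SD, n = 3 each; limma adjusted p = 0.0355). Its symbol was not matched to the annotation used here, and it falls outside the naming rule and was named after its values were seen. The other 2 that rose were the microRNA genes Mir3057 and Mir8105.

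Both microRNA genes were listed at 0 in all 3 WT libraries. They passed the filter through the KO libraries alone, and the WT values added no spread to their test. Neither was called at a pseudocount of 0.1 or with a filter on mean TPM of 1 or more, where 0 genes were called higher by limma. Mir3057 (chromosome 10, 81271597 to 81271687, plus strand) held 1.67, 2.17 and 1.98 TPM in the KO libraries (limma adjusted p = 0.0102). Mir8105 (chromosome 10, 128458680 to 128458768, plus strand) held 1.70, 4.43 and 4.07 TPM (limma adjusted p = 0.0491). These annotated hairpins are 91 and 89 bp long. Mir3057 lies inside Apba3 on the same strand, so reads of the 2 genes cannot be separated here, and Apba3 itself differed by 0.02 on the log2 scale. H19 contains Mir675.

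Among the genes ranked next, none passed the threshold. Higher in KO were Hist1h2ad, a replication-dependent histone gene with near-identical copies that make its value uncertain, listed at 0 in all 3 WT libraries and at 1.31, 1.18 and 2.50 TPM in KO (limma adjusted p = 0.0763), and Slc9a9, an endosomal sodium-proton exchanger, at 0.937 ± 0.133 against 2.36 ± 0.143 TPM (SD, n = 3 each; limma adjusted p = 0.0889). Lower in KO were P2ry14, a receptor for UDP-sugars, at 18.6 ± 5.96 in WT against 4.86 ± 0.816 TPM in KO (limma adjusted p = 0.0542), and Neu2, a sialidase, at 10.6 ± 3.34 against 2.03 ± 0.904 TPM (limma adjusted p = 0.0763). In each of these genes all 3 KO values lay on one side of all 3 WT values.

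An unadjusted p under 0.05 was found for 947 genes, 708 higher and 239 lower, where 449 would be expected by chance. The groups did not overlap in 1485 genes (16.6% of those tested), against 10% by chance, with KO above WT in 1210 and below in 275. The median log2 difference of all tested genes was 0.12, and scaling by the median of ratios brought it to 0.003 and turned the split at unadjusted p under 0.05 to 329 higher and 443 lower. With protein-coding genes alone, rescaled to a common total (an alternative chosen after the data were seen), 38 of 8156 genes were higher and 48 lower, of which 33 were ribosomal protein genes. The median log2 difference in that setting was 0.22, with an unadjusted limma p under 0.05 in 1558 genes higher and 191 lower. With the filter applied after that rescaling, which left 13538 genes, 2 were higher and 4 lower. Leaving out KO library 3 left 0 calls in either direction by limma, with an unadjusted p under 0.05 in 474 genes higher and 203 lower; leaving out WT library 1 left 1 higher, and leaving out KO library 1 or 2 left 0 lower.

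Transcripts of ribosomal proteins, the protein components of the ribosome, were lower in KO as a group. Of 82 tested members 79 had a lower value, and in 76 all 3 KO libraries lay below all 3 WT libraries. Their median log2 difference was -0.55. Rplp1 fell from 651 ± 66.3 to 404 ± 27.2 TPM (SD, n = 3 each), with a limma adjusted p = 0.00921 over the list alone. Rpl36a went from 351 ± 53.8 to 203 ± 13.2 TPM and Rpl37a from 209 ± 14.3 to 130 ± 11 TPM, with the same adjusted p over the list alone. The members with higher values were Rps27l, Rpl32l and Rpl22l1, whose symbols mark them as ribosomal protein-like genes; Rps27l held 12.1 ± 1.82 in WT and 14.5 ± 3.05 TPM in KO. Adjusted over the list alone 74 members fell, and adjusted over all genes tested 0 did by limma, with an unadjusted p under 0.05 in 74. The summed TPM of the list was 24320, 30368 and 26715 in WT and 20065, 18305 and 16881 in KO.

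The list differed from the other genes by camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 1.49e-97), a call lost at adjusted p = 0.357 with an estimated correlation. The median was -0.71 under median-of-ratios scaling and -0.27 under quantile normalization.

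Genes of the extracellular matrix and the basement membrane were higher in KO. Of 26 tested members 25 had a higher value, and the median log2 difference was 0.47, or 0.33 under median-of-ratios scaling and 0.32 under quantile normalization. Adjusted over the list alone 9 rose, and adjusted over all genes tested 0 did by limma, with an unadjusted p under 0.05 in 14. Tnc, which encodes the matrix glycoprotein tenascin C, rose from 0.893 ± 0.231 to 5.16 ± 2.41 TPM and Col18a1, a basement membrane collagen, from 2.09 ± 0.263 to 4.27 ± 0.845 TPM, both with a limma adjusted p = 0.0107 over the list alone (SD, n = 3 each). Lamb1, a laminin chain, rose from 1.61 ± 0.189 to 2.99 ± 0.388 TPM (limma adjusted p = 0.0107 over the list alone). Col15a1, another basement membrane collagen, rose from 11.2 ± 4.46 to 26.8 ± 4.99 TPM (limma adjusted p = 0.0134 over the list alone). Thbs1 was the member with a lower value, at a log2 difference of -0.26.

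The camera call for the matrix list (adjusted p = 3.40e-07, Benjamini-Hochberg) was lost at adjusted p = 0.357 with an estimated correlation. Without WT library 2 the mean difference from the other genes went from 0.37 to 0.23 on the log2 scale. Markers of fibro-adipogenic progenitors and fibroblasts lay at a mean of 3.27, 3.74 and 3.73 log2(TPM + 1) in KO libraries 1, 2 and 3, against 3.09, 3.08 and 3.42 in WT. The Schwann cell markers lay at 1.57, 2.21 and 2.61 in KO and at 1.25, 1.35 and 1.59 in WT. The endothelial markers lay at 1.38, 2.51 and 2.27 in KO and at 1.57, 2.08 and 1.71 in WT.

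**Figure D2:**
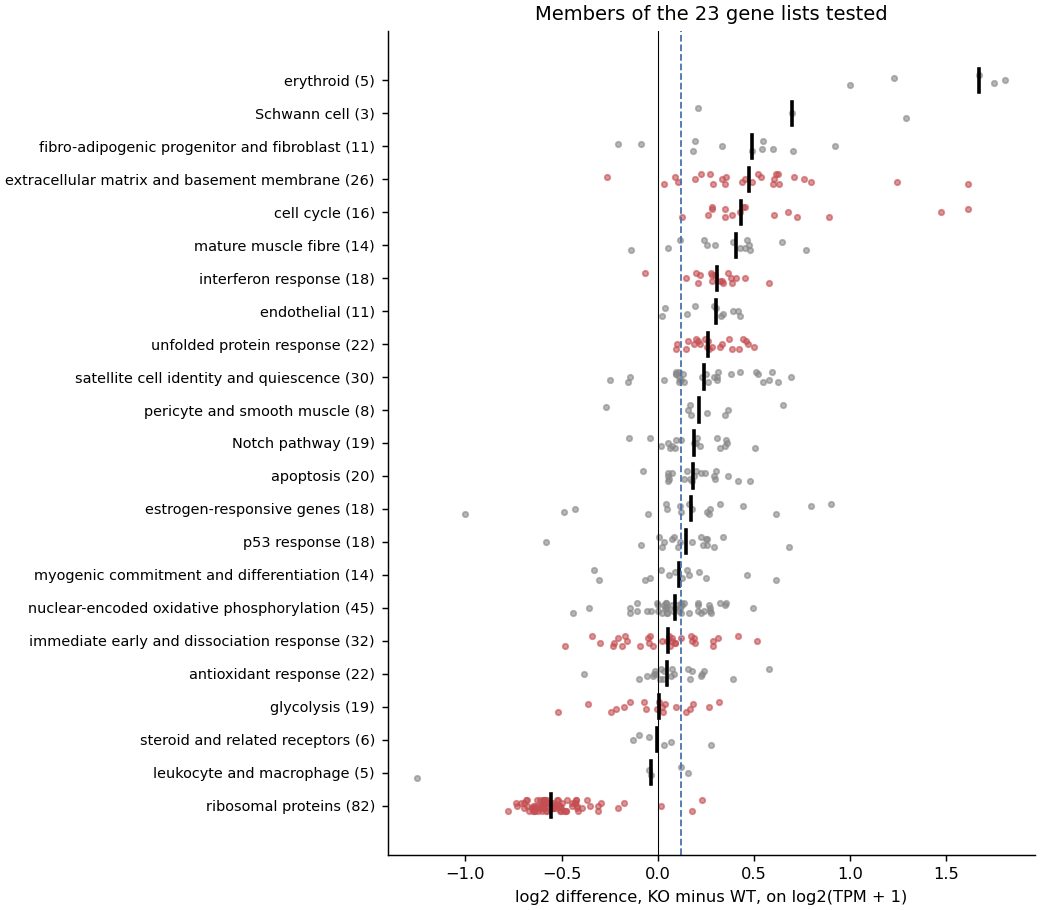
Log2 difference, KO minus WT, on the log2(TPM + 1) scale (x axis) of each tested member (points) of the 23 lists tested (rows, with the number of members); black bars are medians, red marks the 7 lists called by camera with its preset correlation, and the dashed line is the median of all tested genes, 0.12. The ribosomal protein median lies at -0.55 and the matrix median at 0.47.

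Cell cycle genes were higher in KO in all 16 tested members, with a median log2 difference of 0.43, or 0.33 under median-of-ratios scaling and 0.32 under quantile normalization. Adjusted over the list alone 3 rose: Birc5, a mitotic regulator, from 0.997 ± 0.0961 to 2.86 ± 1.40 TPM, Mcm3, a subunit of the replicative helicase, from 1.43 ± 0.208 to 2.96 ± 1.01 TPM, and Hmmr from 2.21 ± 0.345 to 3.39 ± 0.36 TPM (limma adjusted p = 0.0451 over the list alone for each; SD, n = 3 each). Mcm6 did not pass, at 1.59 ± 0.389 in WT and 2.97 ± 0.901 TPM in KO. The proliferation marker Mki67 varied between the KO libraries, at 5.35, 1.59 and 15.3 TPM, against 0.910, 0.410 and 2.47 TPM in WT. Adjusted over all genes tested, 0 members passed by limma, with an unadjusted p under 0.05 in 7. The camera call (adjusted p = 4.43e-05) was lost at adjusted p = 0.783 with an estimated correlation. The mean difference from the other genes was 0.47, and without KO library 3 it was 0.26. KO library 3 also had the highest mean of the Schwann cell markers, 2.61 log2(TPM + 1).

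The unfolded protein response, which acts on misfolded protein in the endoplasmic reticulum, had a higher value in KO in all 22 tested members, with a median of 0.26, or 0.13 under median-of-ratios scaling and 0.16 under quantile normalization. The chaperone Hsp90b1 held 98.5 ± 12.2 in WT and 140 ± 16.4 TPM in KO, and Ddit3, a stress-induced transcription factor, 11.1 ± 1.39 and 15.8 ± 1.21 TPM. Creld2 was at 2.77 ± 0.356 and 4.04 ± 0.184 TPM, and the disulfide isomerase Pdia4 at 8.02 ± 0.770 and 11.3 ± 1.11 TPM (SD, n = 3 each). No member passed by limma over all genes tested or adjusted over the list alone, with an unadjusted p under 0.05 in 6. The camera call (adjusted p = 5.52e-04) was lost at adjusted p = 0.783 with an estimated correlation, and without KO library 1 (adjusted p = 0.154 by camera), where the mean difference from the other genes went from 0.17 to 0.07.

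Interferon response genes had a median of 0.31, or 0.19 under median-of-ratios scaling and 0.20 under quantile normalization, and a higher value in 17 of 18 tested members. Isg15, a ubiquitin-like protein induced by interferon, held 1.74 ± 0.488 in WT and 3.06 ± 0.35 TPM in KO, and the guanylate-binding protein gene Gbp3 0.983 ± 0.205 and 1.70 ± 0.0569 TPM (SD, n = 3 each). Ifi27 was at 7.21 ± 0.987 and 9.53 ± 0.790 TPM. No member passed by limma over all genes tested or adjusted over the list alone, with an unadjusted p under 0.05 in 3. The camera call (adjusted p = 0.00510) was lost at adjusted p = 0.783 with an estimated correlation, and without KO library 2 (adjusted p = 0.0653 by camera), where the mean difference from the other genes was 0.13 against 0.19.

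Glycolysis and the immediate early response were called lower by camera relative to other genes, although their own medians lay slightly above 0. Glycolysis genes had a median of 0.01 and a mean of -0.03 over 19 members. Hk1, a hexokinase, was the member with the smallest p, at 6.65 ± 0.866 in WT and 4.35 ± 0.714 TPM in KO, while Aldoa lay at 34.7 ± 4.53 and 41.8 ± 1.16 TPM (SD, n = 3 each). The immediate early and dissociation genes, which cell isolation itself can induce, had a median of 0.05 and a mean of 0.02 over 32 members. Klf4 held 36.3 ± 6.58 in WT and 25.7 ± 4.63 TPM in KO, and Atf3 82.3 ± 11.6 and 64.5 ± 6.99 TPM. In neither list did a member pass by limma over all genes tested or adjusted over the list alone, with 1 member each at an unadjusted p under 0.05. Under median-of-ratios scaling the medians were -0.15 and -0.10. The camera calls (adjusted p = 0.0118 for glycolysis and 0.0353 for the immediate early list) were both lost, at adjusted p = 0.783 with an estimated correlation. The immediate early call was also lost without WT library 2 (adjusted p = 0.303), WT library 3 (0.134), KO library 1 (0.104) or KO library 3 (0.298), and under quantile normalization its difference turned to 0.002.

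Estrogen-responsive genes did not move together. Of 18 tested members 14 had a higher and 4 a lower value (median 0.17, against a camera direction of down, adjusted p = 0.591; 0.05 under median-of-ratios scaling and 0.03 under quantile normalization). Greb1, a classical target of estrogen receptor α, fell from 1.88 ± 1.03 to 0.380 ± 0.0436 TPM (SD, n = 3 each; limma adjusted p = 0.0321 over the list alone and adjusted p = 0.185 over all genes tested). Its WT values were 3.06, 1.25 and 1.32 TPM. Nrip1, a corepressor of nuclear receptors, lay at 4.68 ± 0.543 in WT and 3.22 ± 0.416 TPM in KO, and Inhbb, an inhibin and activin subunit, at 2.77 ± 0.718 and 1.70 ± 0.550 TPM. Igfbp5 lay at 17 ± 7.08 and 31.3 ± 7.59 TPM. Over all genes tested 0 members passed by limma, with an unadjusted p under 0.05 in 4, and adjusted over the list alone Greb1 was the 1 that did.

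Other steroid and nuclear receptors were not called as a group (median -0.01 and mean 0.02 over 6 members, camera direction down, adjusted p = 0.348). Thra lay at 12.9 ± 1.16 in WT and 15.9 ± 1.97 TPM in KO, the glucocorticoid receptor gene Nr3c1 at 7.74 ± 0.803 and 7.20 ± 1.08 TPM, and Rxrb at 1.87 ± 0.430 and 1.61 ± 0.153 TPM (SD, n = 3 each). No member passed by limma over all genes tested or adjusted over the list alone, and 0 had an unadjusted p under 0.05.

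Satellite cell identity and quiescence genes had a median of 0.24 over 30 tested members, 27 of them with a higher value, against 0.12 for all genes tested; the median was 0.09 under median-of-ratios scaling and 0.10 under quantile normalization. The largest log2 difference was in Dag1, a subunit of the laminin receptor dystroglycan, at 54.0 ± 9.84 in WT and 88.0 ± 16.1 TPM in KO. The caveolin gene Cav1 lay at 23.1 ± 3.13 and 36.0 ± 1.49 TPM, Cd82 at 56.7 ± 9.30 and 80.6 ± 5.80 TPM, and Peg3 at 44.7 ± 9.33 and 66.7 ± 8.06 TPM (SD, n = 3 each). No member passed by limma over all genes tested or adjusted over the list alone, with an unadjusted p under 0.05 in 8, and the camera call missed the threshold (adjusted p = 0.0600, and 0.783 with an estimated correlation). It passed without WT library 3 (adjusted p = 0.00998) and without KO library 1 (adjusted p = 0.0140), and also with no filter (adjusted p = 0.00298), under quantile normalization (adjusted p = 0.0218), and with the filter applied after rescaling of protein-coding genes (adjusted p = 0.00917) or after removal of haemoglobin and ribosomal RNA genes (adjusted p = 0.0144).

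Myogenic commitment genes were not called as a group (14 members, median 0.11, camera direction down, adjusted p = 0.838). By fry their direction was up, with an unadjusted p of 0.0247 and an adjusted p of 0.181. Myod1, a myogenic transcription factor, lay at 94.7 ± 6.89 in WT and 76.8 ± 20.6 TPM in KO, Chrna1, an acetylcholine receptor subunit, at 3.25 ± 0.940 and 5.50 ± 1.30 TPM, Myl4 at 0.803 ± 0.357 and 1.45 ± 0.0987 TPM, and Mef2d at 6.22 ± 1.42 and 7.51 ± 0.810 TPM. The Notch pathway, which maintains satellite cell quiescence, had a median of 0.19 over 19 members (camera adjusted p = 0.25), or 0.04 under median-of-ratios scaling and 0.05 under quantile normalization. Notch1 lay at 7.03 ± 1.5 and 10.3 ± 0.892 TPM, Jag1 at 6.42 ± 1.07 and 8.46 ± 0.437 TPM, Ncstn at 4.60 ± 0.201 and 5.95 ± 0.637 TPM, and Notch3 at 16.8 ± 2.25 and 21.6 ± 1.64 TPM (SD, n = 3 each). No member of either list passed by limma over all genes tested or adjusted over the list alone, with an unadjusted p under 0.05 in 2 myogenic and 4 Notch members. The myogenic median was -0.01 under median-of-ratios scaling and -0.02 under quantile normalization.

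Apoptosis, the p53 response, oxidative phosphorylation and the antioxidant response were not called by camera. None of their members passed by limma over all genes tested or adjusted over the list alone, with an unadjusted p under 0.05 in 2, 1, 3 and 1 members. Apoptosis genes had a median of 0.18 over 20 members (adjusted p = 0.227), or 0.05 under both median-of-ratios scaling and quantile normalization. Bcl2l1, which restrains apoptosis, lay at 1.22 ± 0.175 in WT and 1.88 ± 0.420 TPM in KO, and Diablo, which promotes it, at 1.73 ± 0.276 and 2.64 ± 0.367 TPM. The p53 response had a median of 0.15 over 18 members (adjusted p = 0.761), or 0.04 and 0.05, with Eda2r at 2.81 ± 1.0 and 5.04 ± 0.910 TPM. Nuclear-encoded oxidative phosphorylation had a median of 0.09 over 45 members (camera direction down, adjusted p = 0.719) and of -0.05 under median-of-ratios scaling, with the cytochrome c oxidase subunit Cox4i1 at 52.9 ± 5.86 and 38.7 ± 2.39 TPM. The antioxidant response had a median of 0.05 over 22 members (camera direction down, adjusted p = 0.386, and 0.0319 without KO library 1) and of -0.08 under median-of-ratios scaling, with Hmox1 at 195 ± 70.5 and 298 ± 143 TPM (SD, n = 3 each).

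Markers of other cell types in muscle varied between libraries, and no such list was called with the TPM and the filter used here. Schwann cell markers had 3 tested members, of which 2 rose when adjusted over the list alone, among them Mbp, which encodes a myelin protein (limma adjusted p = 0.0338), and 0 passed over all genes tested, with an unadjusted p under 0.05 in 2. Mbp was at 1.72, 2.22 and 1.95 TPM in WT and 2.24, 3.91 and 5.98 TPM in KO; the list had a camera adjusted p of 0.0600. Among fibro-adipogenic and fibroblast markers (11 members, median 0.49, camera adjusted p = 0.238), Dpt, a matrix protein gene, rose from 26.8 ± 3.91 to 44.2 ± 6.01 TPM (limma adjusted p = 0.0247 over the list alone). Dcn lay at 8.26, 13.4 and 8.66 TPM in WT and 7.32, 13.03 and 8.23 TPM in KO. Muscle fibre markers (14 members, median 0.41, camera adjusted p = 0.384) had one member that rose over the list alone, Actn3, from 4.64 ± 1.06 to 8.52 ± 0.539 TPM (SD, n = 3 each). Acta1, the fibre's own actin, lay at 3.01, 5.29 and 8.86 TPM in WT and 1.78, 11.6 and 11.1 TPM in KO. Other settings and single libraries moved these results. Camera called the Schwann list with no filter (adjusted p = 0.00388), under median-of-ratios scaling (0.0197) and quantile normalization (0.0218), with library weights (0.0477) and with protein-coding genes filtered after rescaling (0.0342). It called the fibro-adipogenic list without WT library 3 (adjusted p = 0.00931), the fibre list without WT library 3 (adjusted p = 0.00998) or KO library 1 (adjusted p = 9.50e-07), and the Schwann list without WT library 3 (adjusted p = 0.0115) or KO library 1 (adjusted p = 0.00145).

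The remaining marker lists had no member past the limma threshold over all genes tested or adjusted over the list alone, and 1 member, of the pericyte list, at an unadjusted p under 0.05. Erythroid markers (5 members, median 1.67, camera adjusted p = 0.144) followed single libraries: Hba-a1, a haemoglobin gene, was at 83.4, 18.15 and 6.31 TPM in WT and 164, 168 and 15.04 TPM in KO. Endothelial markers had a median of 0.30 over 11 members (camera adjusted p = 0.591), and, without KO library 1, an adjusted p = 0.000152 by camera. Pericyte and smooth muscle markers had a median of 0.22 over 8 (camera adjusted p = 0.591). Leukocyte and macrophage markers had a median of -0.03 over 5 members (camera adjusted p = 0.238), with S100a9 at 5.55 ± 5.09 in WT and 1.05 ± 1.10 TPM in KO (SD, n = 3 each). Camera called the erythroid list higher with no filter (adjusted p = 0.0307), under median-of-ratios scaling (0.0248) and quantile normalization (0.0218), and the leukocyte list lower at a mean TPM of 1 or more (0.04998) and with haemoglobin and ribosomal RNA genes removed before the filter (0.00811). It called the erythroid list higher without WT library 1 (adjusted p = 0.000344) or KO library 3 (adjusted p = 2.31e-06) and the leukocyte list lower without WT library 1 (adjusted p = 0.000138) or KO library 3 (adjusted p = 0.0407). Of the tenocyte markers Thbs4 lay at 1.77 ± 0.396 and 3.34 ± 1.89 TPM and Fmod at 1.03 ± 0.310 and 1.31 ± 0.669 TPM. Xist, transcribed from the inactive X chromosome, was at 27.1 ± 2.68 and 27.5 ± 2.83 TPM, and the Y-linked Kdm5d and Eif2s3y were listed at 0 in all 6 libraries. None of the mitochondrially encoded transcripts was among the symbols used here.

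**Figure D3:**
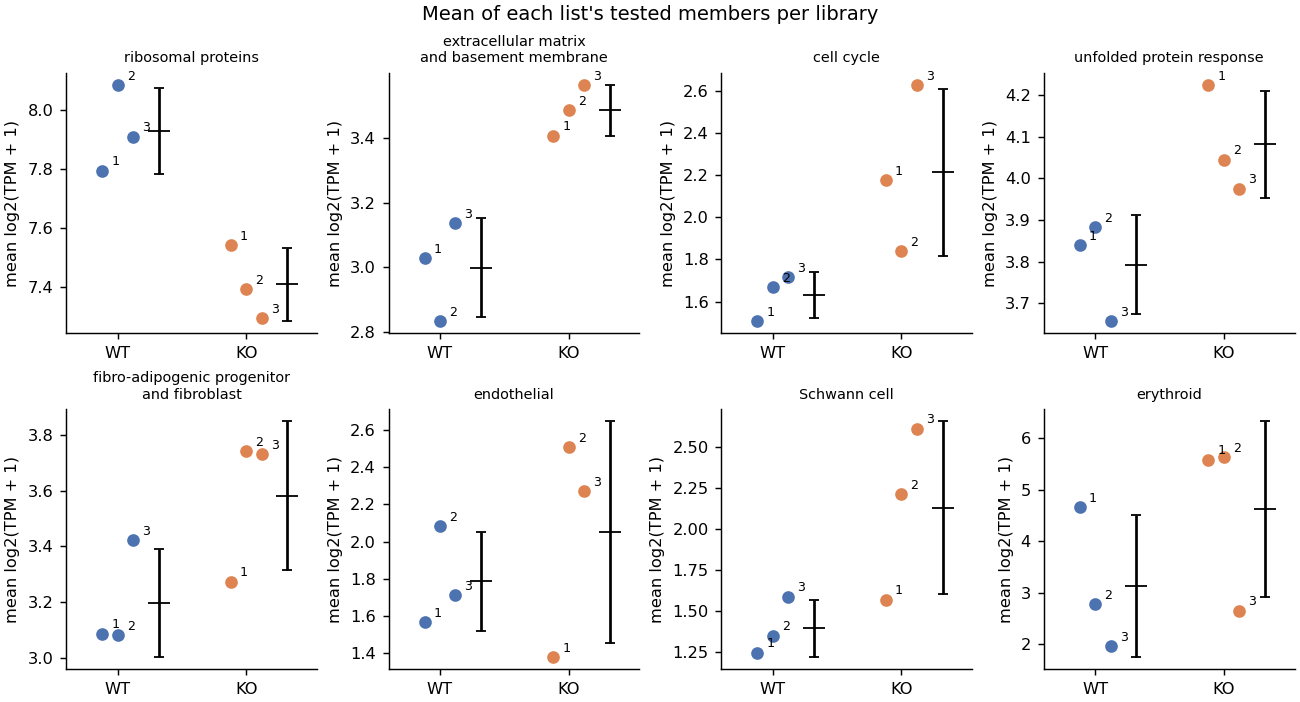
Mean log2(TPM + 1) of the tested members of 8 lists (y axis) in each WT and KO library (points, numbered by replicate), with the group mean ± SD in black. The ribosomal protein, matrix, cell cycle and unfolded protein response means of the 2 groups do not overlap, while the endothelial mean is lowest in KO library 1, at 1.38, and highest in KO library 2, at 2.51.

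The libraries resembled one another. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, lay between 0.950 and 0.973 for all pairs of libraries, and the highest was between WT library 1 and KO library 1. Within WT they lay between 0.964 and 0.973 and within KO between 0.960 and 0.966. The first principal component held 30.3% of the variance and placed the WT libraries at -14.96, -3.07 and -21.6 and the KO libraries at 5.44, 20.5 and 13.7. The second held 24.8%, with WT library 2 and KO library 3 at its ends.

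**Figure D4:**
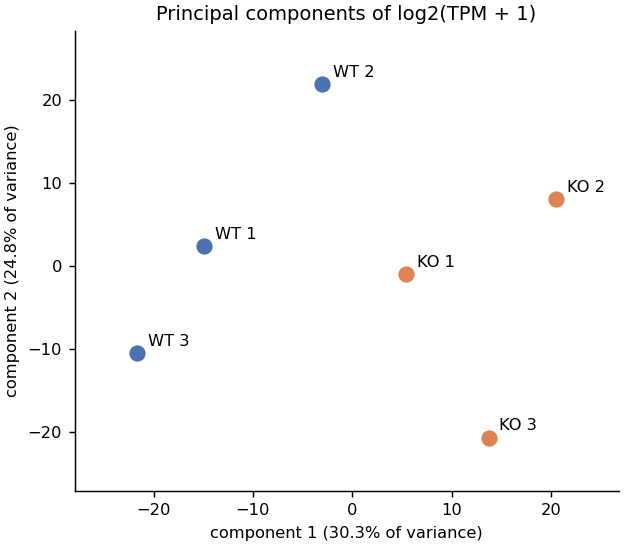
Scores of the 6 libraries on the first (x axis) and the second (y axis) principal component of log2(TPM + 1) over the genes tested, WT in blue and KO in orange. The 3 WT libraries lie below 0 and the 3 KO libraries above 0 on the first component, which holds 30.3% of the variance.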

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

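The alternatives with protein-coding genes only and those with the filter applied after rescaling were tests chosen after the data were seen. Of the 7 lists called by camera, ribosomal proteins and extracellular matrix kept their calls under all 20 other scalings, filters, fits and libraries left out, these included, with adjusted p up to 5.46e-36 and up to 0.00692, and lost them with an estimated correlation (adjusted p = 0.357 for both). Fry, which asks whether a list moves one way and compares it with no other genes, gave them adjusted p = 0.1004 and 0.0899. Calls of single genes (limma, 3 higher and 2 lower) were not stable. They were 0 and 0 with no filter, with a mean TPM of 1 or more, and with haemoglobin and ribosomal RNA genes removed, where 1198 and 374, 723 and 243, and 1593 and 201 genes had an unadjusted p under 0.05. Other counts of genes higher were 0 at a pseudocount of 0.1 and 1 each at TPM of 5 or more, under the median of ratios and under quantile normalization. Genes lower were 0 at a pseudocount of 5 and under quantile normalization, and 1 under the median of ratios. Robust eBayes gave 17 higher and 16 lower, library weights 53 and 27, and protein-coding genes only 38 and 48. With the filter applied after rescaling, protein-coding genes only gave 2 and 4, and removal of haemoglobin and ribosomal RNA genes 5 and 4. The weights gave WT library 1 a value of 4.10 and WT library 2 0.410. Leaving out 1 library gave between 0 and 4 genes higher and between 0 and 2 lower: 1 and 2 without WT library 1, 4 and 2 without WT library 2, 3 and 1 without WT library 3, 3 and 0 without KO library 1, 4 and 0 without KO library 2, and 0 and 0 without KO library 3. Esr1 stayed lower in 20 alternatives, from -1.02 to -0.52, with limma adjusted p from 0.0222 to 0.319, and passed in 3 (robust eBayes -0.86, adjusted p = 0.0240; library weights -0.86, 0.0222; protein-coding only -0.96, 0.0359). Lists called were 4 at TPM of 5 or more, where fewer genes were tested, 0 with an estimated correlation and, by the different question of fry, 0. The immediate early list turned from -0.10 to 0.00207 under quantile normalization, and by fry its direction was up, with the difference at -0.10. Besides the losses by library given with each list, glycolysis lost its call with no filter (adjusted p = 0.129), with haemoglobin and ribosomal RNA genes removed (0.0506, or 0.172 with the filter after rescaling) and with protein-coding genes filtered after rescaling (0.126). Cell cycle and interferon lost theirs at TPM of 5 or more (0.601 and 0.274), and the unfolded protein response with library weights (0.159). The immediate early list lost its call with no filter (0.204), at TPM of 5 or more (0.0504), with haemoglobin and ribosomal RNA genes removed (0.116, or 0.288 with the filter after rescaling), with library weights (0.244) and with protein-coding genes filtered after rescaling (0.194). Results not called also changed sign, 40 times in 12 lists and 25 times in 11 named genes. The cause of these changes was not tested. The depth is unknown, and values near 1 TPM, as in Car12 and the microRNA genes, are the least certain.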

Other observations

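The gene families, the single genes and the tests of the matrix list in this part were chosen after their values, or those of the markers they rest on, had been seen; the tests on matched genes, nuclear RNAs, TOP mRNAs and the imprinted genes not looked at before were fixed before their results, although Xist, Malat1 and the oxidative phosphorylation genes among them had been seen. Replication-dependent histone genes, whose mRNAs accumulate in S phase, were higher in KO in 48 of 50 tested members, with a median log2 difference of 1.02, and 0.89 and 0.87 under median-of-ratios scaling and quantile normalization. Hist1h2af lay at 3.01, 2.33 and 4.21 TPM in WT and 17.4, 6.13 and 31.3 TPM in KO, and Hist1h4n at 0.390, 0 and 0.140 against 10.1, 1.69 and 5.54 TPM. In 9 of the 50 the groups did not overlap, where chance gives 10% and all genes tested gave 16.6%. Camera over 11 symbol families gave an adjusted p of 2.63e-08, and 0.825 with an estimated correlation. The mean of the family per library, on log2(TPM + 1), was 1.63, 1.73 and 2.27 in WT and 2.94, 1.88 and 3.86 in KO, beside cell cycle means of 1.51, 1.67 and 1.71 and of 2.18, 1.84 and 2.63. These genes have near-identical copies, so single members are uncertain. Small nucleolar RNAs had a lower value in 79 of 112 members (median -0.16, camera adjusted p = 3.53e-18, and 0.209 with an estimated correlation). Their median was -0.32 under median-of-ratios scaling but -0.003 under quantile normalization. MicroRNA hairpins were called lower by camera (adjusted p = 0.00673, and 0.825 with an estimated correlation) with a median of 0.16 over 223. Collagens had a higher value in 16 of 17 (median 0.43, adjusted p = 0.00134, and 0.825 with an estimated correlation), and some of them are in the matrix list. The other 7 families were not called.

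Several single genes had groups that did not overlap without passing the adjusted threshold over all features. Gpam, an enzyme of glycerolipid synthesis, lay at 5.22 ± 2.73 in WT and 0.880 ± 0.233 TPM in KO (limma adjusted p = 0.115), while the sterol synthesis genes Hmgcs1 and Sqle differed by 0.18 and 0.12 on the log2 scale. Nr1d1, a repressor of the circadian clock, lay at 5.35 ± 0.215 and 9.74 ± 1.11 TPM (limma adjusted p = 0.115), with the clock genes Per1, Per2, Arntl and Dbp at differences of 0.46, 0.07, 0.05 and 0.02; in Per1 too all KO values lay above all WT values (5.33 ± 1.52 and 7.52 ± 0.605 TPM, limma adjusted p = 0.448). The potassium channel subunit Kcne4 lay at 6.07 ± 1.12 and 2.04 ± 0.610 TPM, the prostaglandin transporter Slco2a1 at 7.11 ± 2.01 and 2.44 ± 0.410 TPM, the intermediate filament gene Nes at 1.33 ± 0.215 and 3.63 ± 1.21 TPM, and Gfra1, a receptor for glial-derived neurotrophic factor, at 3.24 ± 0.737 and 6.72 ± 0.322 TPM (SD, n = 3 each). Nnt, in which C57BL/6J mice carry a known deletion, lay at 0.810, 1.36 and 0.920 TPM in WT and 1.97, 2.05 and 2.02 TPM in KO. With protein-coding genes alone, rescaled to a common total, the genes called also included Tnc (log2 difference 2.35), Gpam (-2.28), Slco2a1 (-1.42), Kcne4 (-1.49), Nes (1.41), Gfra1 (1.11), Nr1d1 (0.91), Nnt (0.99) and Mest (1.49), in a setting where 38 genes were higher and 48 lower, against 2 and 4 with the filter applied after rescaling. The median of all genes in that setting was 0.22. Under a common total, lower ribosomal protein values raise those of all other genes, so the higher differences there are in part relative.

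The lower ribosomal protein transcripts (median -0.55) were set against a technical and a biological reading. Their short length argues against itself as the cause: 366 protein-coding genes matched to 81 of the 82 members on transcript length and GC content had a median of 0.12 (95% bootstrap interval 0.09 to 0.14), although they were far less abundant, with a median of 3.58 against 255 TPM. The bootstrap intervals here and below resample genes, not libraries, so they leave out the spread between libraries. A larger nuclear share of RNA in KO is argued against by 14 nuclear-retained long RNAs, whose median was 0.0769 (0.03 to 0.15, and -0.05 and -0.06 under median-of-ratios scaling and quantile normalization), and by oxidative phosphorylation mRNAs at 0.09 (-0.05 and -0.06). Of the 14, 11 had a higher and 3 a lower value. Malat1, the most abundant, lay at 582 ± 158 in WT and 727 ± 128 TPM in KO, a log2 difference of 0.34 with overlapping groups. Xist, Neat1 and Lncpint differed by 0.02, -0.03 and 0.09. Several others had low values, where the log2(TPM + 1) scale shrinks a shift, so a small shift stays possible. TOP mRNAs, which carry the same 5' terminal oligopyrimidine motif as ribosomal protein mRNAs, were lower where they encode no ribosomal protein: 21 of 22 had a lower value, with a median of -0.34 (-0.45 to -0.17), as in Eef2 at 332 ± 51.2 and 226 ± 18.7 TPM and Rack1 at 207 ± 17.9 and 136 ± 15.4 TPM. A shared change of TOP mRNAs, with or without a link to the genotype, is therefore a hypothesis that stays open, as does a cause common to very abundant transcripts, for which no set matched on abundance was tested.

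For the higher matrix list the candidate sources weighed were fibroblast, endothelial and Schwann cell RNA that passed the sort. With the endothelial marker score as a covariate the list's difference from other genes was 0.41, against 0.37 without it. The endothelial score thus did not account for the difference in this fit, which has the same few degrees of freedom as those below. KO library 1 had the lowest endothelial mean, 1.38, and a matrix mean of 3.41 log2(TPM + 1), against 3.03, 2.83 and 3.14 in WT. With the fibroblast score as a covariate it was 0.23, or 63.2% of its size, and with the score of 3 Schwann cell markers (Mbp at 1.96 ± 0.25 in WT and 4.04 ± 1.87 TPM in KO) 0.27, or 72.1%, which decides neither way. The 5 most abundant fibroblast markers, Gsn, Col3a1, Serping1, Dpt and Dcn, had log2 differences of -0.21, 0.18, 0.20, 0.70 and -0.09, the median of all 11 markers was 0.49, and satellite cells also express part of both lists. Fibroblast RNA, Schwann cell RNA and a change of the satellite cells with genotype cannot be told apart, since 6 libraries leave few degrees of freedom for a covariate that itself differs between the groups.

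Imprinted genes other than H19 stood out among those looked at first: Rian lay at 25.1 ± 3.65 in WT and 47.3 ± 1.51 TPM in KO, Meg3 at 34.0 ± 9.09 and 62.1 ± 9.80, and Mest at 2.51 ± 0.506 and 7.09 ± 2.42 TPM, and 9 of 15, H19 included, had all KO values above all WT values, against 1210 of all 8971 genes tested. Of the 15, 3 had a lower value: Cdkn1c, Peg10 and Dcn, at log2 differences of -0.31, -0.15 and -0.09. Over 20 imprinted genes not looked at before, the median lay 0.0475 above that of all genes (95% bootstrap interval over genes -0.01 to 0.10). That argues against a shared change of imprinted genes at large of the size seen in the first 15, whose median lay 0.40 above that of all genes. Of the 20, 18 had a higher value, 13 lay above the median of all genes, and in 4 all KO values lay above all WT values. Many of the 20 had low values, where the log2(TPM + 1) scale shrinks a change, so a smaller shared change is not excluded. One of these 20, Zim1, a neighbour of Peg3, lay at 7.62 ± 1.96 in WT and 12.6 ± 1.20 TPM in KO. A larger nuclear share of RNA is argued against by the same nuclear-retained RNAs, at 0.0769, with the limits given above. Whether H19, Meg3, Rian, Mest and Peg3 form a smaller group that differs with genotype stays open and untested, since they were picked from these libraries.

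Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 5 genes and the others between 0 and 12. Of the 10 splits, 5, the real one included, gave at least as many genes as the real one. For lists the real split called 7 and the others between 3 and 13, so every other split called lists too. Again 5 of the 10, the real one included, gave at least as many. The number of calls, of genes or of lists, therefore does not set the grouping by genotype apart from other groupings.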
